A study of Homo sapiens with 2 samples.

How the data were processed

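Poly-A RNA of PC9-BrM3 lung cancer cells with PCDH1 knockdown (shPCDH1) and control cells (shNC) was sequenced, with 1 GEO sample per group. The library protocol in the labels used unmodified dNTP in second strand synthesis, so strand is not marked, and genes that overlap on opposite strands cannot be told apart. Reads were handled with CASAVA, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0, per the submitters' processing notes, which give no roles, order or parameters. The genome build and annotation the authors used are not given in the sources used here. All 27655 gene identifiers and names in the deposited table match GENCODE release 29 (GRCh38), and 27651 genes have the same start and end there, so coordinates are given on that build.

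The deposited table holds, per the file headers, a log2 fold change of a group coded 8 over a group coded 7 for each gene, made by the authors. It also holds the authors' p-value and adjusted p-value for each gene, both deposited per the file headers. DESeq2 was used by the authors, per the submitters' processing notes, and no count model was fitted here. Adjusted p-values below 1 were given for 18002 genes, and the leading ones equal the deposited p multiplied by that number and divided by rank. The other 9653 genes are listed at an adjusted p of 1, 174 of them with an unadjusted p under 0.05, and 2 genes have no p-value. Other deposited columns, gene length, start and end, are annotation of the gene made by the authors, in bases and chromosome positions. The 20 columns with values per library or per coded group were not used in any step, because no label ties the 6 library codes or the group codes to shPCDH1 or shNC. Depth per library is therefore not given, genes were not matched or filtered on level, and folds of genes near 0 in one group may be extreme.

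A standard error was computed for each gene as the absolute log2 fold change divided by the normal quantile of the deposited two-sided p-value, which assumes a Wald test. The sources used here do not state the authors' test. Calls are the authors' adjusted p under 0.05. For each of 32 gene lists, members were matched by symbol, or by Ensembl identifier through a table of current symbols. 764 genes of the lists were measured. The number of members called in each direction was counted, and again with Benjamini-Hochberg adjustment over the members' deposited p-values (adjusted over the list alone). The list's median log2 fold change was placed among the medians of 10000 random lists of the same size drawn from all genes, unmatched since no level was used. This percentile is a description of these values and not a p-value, and chance alone puts about 1.6 of 32 lists of unrelated genes outside the middle 95%. The lists, the calling threshold, the alternative settings and the rule for named genes were fixed before the data were examined. That rule names PCDH1, the 12 highest and 12 lowest protein-coding genes by log2 fold change with an adjusted p under 0.05, the 10 protein-coding genes with the smallest adjusted p, and up to 4 called members per list with the smallest adjusted p, leaving out XIST and genes of the Y chromosome. It named 134 genes, some of which are not reported here. The minimum level it foresaw was not applied because levels were not used. Members with no call and genes in the closing section were chosen after their values were seen.

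The alternative settings fixed then were adjusted p thresholds of 0.01 and 0.10, minimum absolute log2 fold changes of 1 and 0.5, protein-coding genes alone, Benjamini-Hochberg adjustment over every deposited p-value, random lists from protein-coding genes, centring on the protein-coding median, means in place of medians, and protein-coding members with an adjusted p below 1. Alternatives needing library values were left out. Added after seeing the data were random lists matched in 20 bins of implied standard error, removal of a quadratic trend with gene length and transcript GC, and counts without genes whose 3' UTR holds the word GACGTC.

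The longest 3' UTR of each gene's basic protein-coding GENCODE transcripts was searched for words of 6 and 7 bases in 13381 protein-coding genes with an adjusted p below 1 and a 3' UTR of at least 50 bases. Log2 fold changes were limited to 2 in size and adjusted for length and GC, and each word held by at least 50 genes and at most 60% of genes was scored for lower or higher values, against 1000 shufflings of the genes' values. These settings were chosen after the list values had been seen. The same procedures were tested on simulated data. Of 200 unchanged lists of 30 genes drawn from the 27655 genes, 5% fell outside the middle 95%, and 85% of 200 lists shifted by 0.5 (log2) passed above it. These lists were drawn in the same way as the reference lists, so the 5% checks the computation only, not lists of genes that vary together. All 20 words of 7 bases planted with a shift of 0.3 (log2) in shuffled values over 13381 genes were ranked first. Each planted word was held by 200 to 1000 genes, so rarer and commoner words were not tried. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.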

Results

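RNA from PC9-BrM3 cells, a brain-metastatic derivative of the PC9 lung adenocarcinoma line, was sequenced as poly-A selected libraries from cells carrying a hairpin against PCDH1 (shPCDH1) and control cells (shNC). GEO lists 1 sample per group. The comparison asked how the transcriptome of these cells differs with and without knockdown of PCDH1. Values are those of the authors' deposited table, which compares a group coded 8 with a group coded 7. No label ties either code, or any of the 6 library codes in its header, to shPCDH1 or shNC, so direction is written throughout as group 8 relative to group 7. The 20 columns of levels per library or group were not used here, so depth per library is not given. Each fold change is followed by the standard error implied by the authors' p-value under a Wald test, an assumption, since the test is not stated in the sources used here.

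PCDH1, a protocadherin that mediates cell-cell adhesion (ENSG00000156453, chromosome 5, 141853111 to 141879246, minus strand), had a log2 fold change of -1.38 ± 0.14 in the authors' deposited table. Its level in group 8 was 38.5% of that in group 7, or 2.6-fold lower, with an adjusted p of 1.76e-20. This value does not by itself assign the codes to the labels. In the authors' deposited table, 3887 of 27655 genes had an adjusted p under 0.05, of which 1875 were higher and 2012 lower in group 8. With an absolute log2 fold change of at least 1, 647 were higher and 431 lower, so that 60.0% of calls were higher against 48.2% without that minimum. The median log2 fold change of protein-coding genes was 0.017. Since GEO lists 1 sample per group, nothing states that the libraries came from separate cultures, and the authors' p-values measure only the spread between libraries, which may be technical.

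The highest protein-coding genes in group 8 included acute-phase, cytokine and other immune genes. SAA1 and SAA2, which encode serum amyloid A proteins, had log2 fold changes of 7.81 ± 1.23 and 7.20 ± 1.07. As near-identical copies they can share reads, so their split is uncertain. The cytokine gene TNF was 141-fold higher at 7.14 ± 0.68, and S100A8, a calprotectin subunit, was 66.3-fold higher at 6.05 ± 0.52. The other 8 of the 12 highest were VNN1 at 6.83 ± 1.33, PRAME at 6.42 ± 1.40, MYCBPAP at 6.23 ± 1.39, SERPING1, the C1 inhibitor, at 6.06 ± 1.34, DRC7 at 5.96 ± 1.33, LST1 at 5.92 ± 1.46, the chemokine CCL20 at 5.87 ± 1.45 and the interferon-induced IFI27 at 5.76 ± 1.48. Their standard errors of 1.33 to 1.48 leave the size of the fold poorly fixed.

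The 12 lowest genes included epithelial and matrix genes. KRT4, an epithelial keratin, was 13.7-fold lower at -3.78 ± 0.31. ALDH1A1, a retinaldehyde dehydrogenase, was 8.35-fold lower at -3.06 ± 0.13, and TIMP3, an inhibitor of metalloproteinases, 7.93-fold lower at -2.99 ± 0.13. GUCY1A2, a subunit of soluble guanylate cyclase, had -4.18 ± 1.30, the adhesion gene CEACAM5 -3.61 ± 1.02, TENM4 -3.31 ± 0.87, LRRC4 -3.27 ± 0.50 and IGLON5 -3.04 ± 0.65. MMP9, a gelatinase, had -3.02 ± 0.68, the keratin gene KRT23 -2.97 ± 1.01, the claudin gene CLDN8 -2.97 ± 0.93 and RGCC -2.89 ± 0.39.

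The smallest adjusted p in the authors' deposited table was that of C3, the central complement component, at 3.77 ± 0.14 and an adjusted p of 1.2e-162. BCAT1, the cytosolic branched-chain aminotransferase, followed among the higher genes at 4.10 ± 0.18, then TNFAIP3, a feedback inhibitor of NF-kB, at 3.65 ± 0.19, PI3, the protease inhibitor elafin, at 5.23 ± 0.27, the chemokine CXCL8 at 3.81 ± 0.20 and HLA-B, a class I antigen-presenting molecule, at 4.10 ± 0.24. HLA genes share reads between alleles and family members, so the HLA-B value is uncertain in size. Among the lower genes, ALDH1A1 and TIMP3 had adjusted p values of 4.48e-119 and 4.6e-114, and the aldo-keto reductases AKR1B10 and AKR1C3 had log2 fold changes of -2.22 ± 0.12 and -2.18 ± 0.12. AKR1C family members are close paralogs, which limits the AKR1C3 value.

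In the searched 3' UTRs, the word GACGTC was present in 210 of 1793 protein-coding genes called lower in group 8 and in 80 of 1705 called higher. This property was found after the values were seen, and 794 of all 13381 searched genes held the word. Named genes that hold it were PCDH1, GUCY1A2, CLDN8, AKR1C3, SPRED2, ACSL3 and SLC7A5, which were lower, and BNIP3 and MUC1, which were higher.

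**Figure D1:**
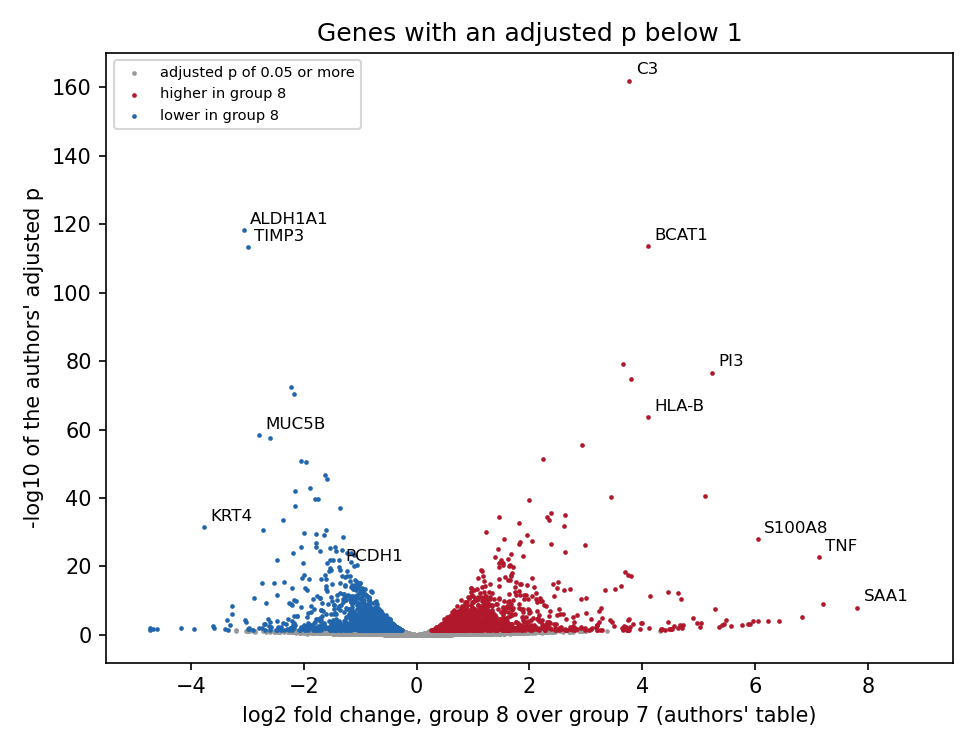
Each point is a gene with an adjusted p below 1 in the authors' table, placed by log2 fold change of group 8 over group 7 (horizontal axis) and by -log10 of the adjusted p (vertical axis). Of these, 1875 were higher (red) and 2012 lower (blue) at an adjusted p under 0.05, with C3 highest on the vertical axis.

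**Figure D2:**
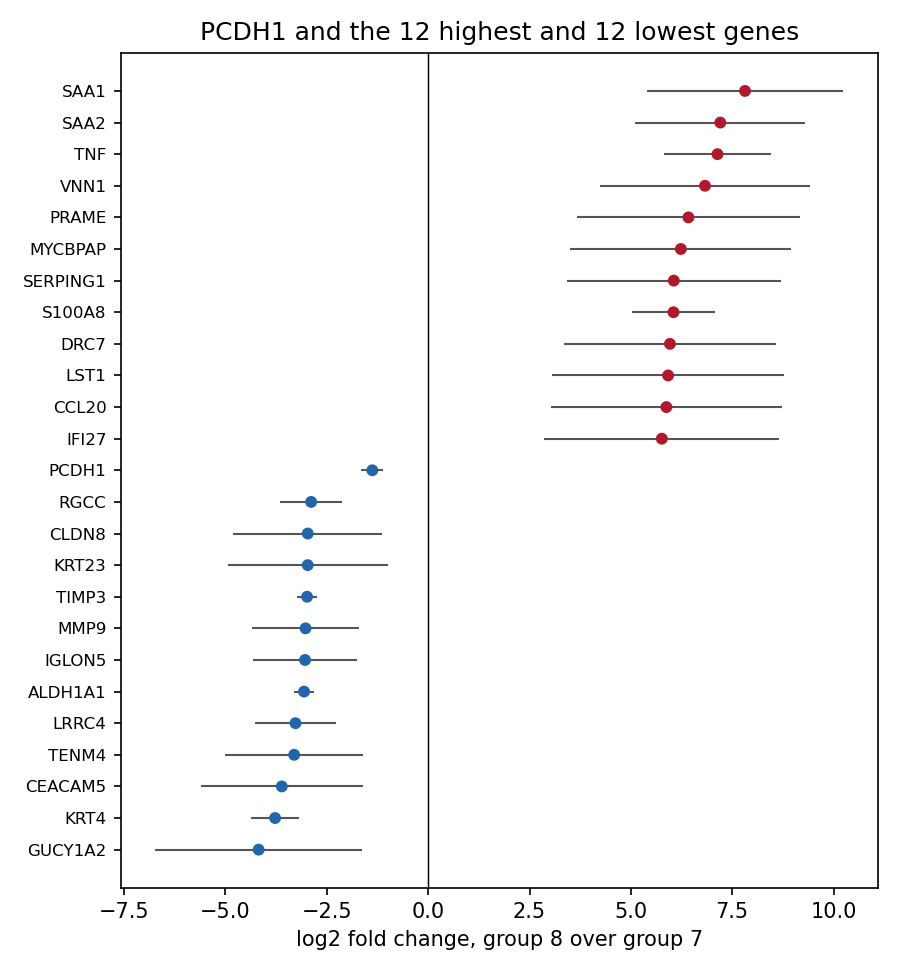
Points give the log2 fold change of group 8 over group 7 for PCDH1 and the 12 highest and 12 lowest protein-coding genes with an adjusted p under 0.05, and bars span the 95% interval from the implied standard error. SAA1 lies at 7.81, GUCY1A2 at -4.18 and PCDH1 at -1.38.

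Inflammatory genes were higher in group 8. Medians below are log2 fold changes, and percentiles place them among the medians of 10000 random lists of the same size. Of 32 lists, 3 lay above and 4 below the middle 95%, where chance puts about 1.6 if members are unrelated. Lists of genes that vary together can fall outside more often. For NF-kB target and cytokine genes, 22 were higher and 0 lower among 30 measured members, and 22 and 0 when adjusted over the list alone, with a median of 1.93 at percentile 100. Besides TNF, CXCL8 and TNFAIP3, the chemokine CXCL1 had 5.11 ± 0.37 and BIRC3, an inhibitor of apoptosis, 2.38 ± 0.18. For interferon-stimulated genes, 24 were higher and 0 lower among 38 measured members, and 26 and 0 when adjusted over the list alone, with a median of 1.04 at percentile 100. Examples were IFI6 at 3.44 ± 0.25, the transcription factor IRF1 at 1.64 ± 0.21, the antiviral GTPase MX1 at 1.62 ± 0.25 and OAS3 at 0.80 ± 0.13. In the leukocyte marker list, 2 were higher and 0 lower among 13 measured members, and 2 and 0 when adjusted over the list alone, with a median of 0.78 at percentile 99.3. The called members were ITGAM at 5.28 ± 0.85 and CSF1R at 1.84 ± 0.24, while PTPRC, the pan-leukocyte CD45 gene, had -0.12 ± 0.69 and CD14 -0.062 ± 0.50 with no call. That list's median was 0.53, at percentile 90.2, over protein-coding members with an adjusted p below 1.

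Growth factor and redox genes were lower in group 8. For EGFR/MAPK output genes, 3 were higher and 15 lower among 30 measured members, and 3 and 16 when adjusted over the list alone, with a median of -0.52 at percentile 0.04. The early response gene EGR1 had -1.26 ± 0.18, SPRED2, an inhibitor of this pathway, -0.85 ± 0.13 and the EGFR ligand AREG -1.47 ± 0.22, whereas the ligand TGFA was higher at 0.97 ± 0.16. For NRF2 target and ferroptosis genes, 1 was higher and 17 lower among 28 measured members, and 1 and 18 when adjusted over the list alone, with a median of -0.56 at percentile 0.02. ALDH3A1, an aldehyde dehydrogenase, had -2.36 ± 0.19 and AKR1C1 -1.24 ± 0.11. For DNA replication and mitosis genes, 1 was higher and 16 lower among 45 measured members, and 2 and 17 when adjusted over the list alone, with a median of -0.24 at percentile 1.16. The replicative helicase genes MCM5 and MCM3 had -1.05 ± 0.17 and -0.55 ± 0.12, GINS2 had -0.77 ± 0.14 and PCNA, the sliding clamp, -0.47 ± 0.10. With the mean in place of the median, this list lay at percentile 4.90. For lung lineage genes, 3 were higher and 3 lower among 23 measured members, and 4 and 5 when adjusted over the list alone, with a median of -0.48 at percentile 0.30. The mucin gene MUC5B had -2.79 ± 0.17 and the transcription factor FOXA1 -0.89 ± 0.14, while MUC1 and LAMP3 were higher at 1.23 ± 0.17 and 1.24 ± 0.24. Restricted to protein-coding members with an adjusted p below 1, its median was -0.29 at percentile 5.55.

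The other 25 lists lay inside the middle 95% of random lists drawn from all genes. Adhesion lists held changes in both directions. For protocadherins and classical cadherins, 3 were higher and 4 lower among 23 measured members, and 4 and 5 when adjusted over the list alone, with a median of -0.22 at percentile 6.38. The list includes the targeted gene PCDH1, and lay at percentile 2.25 against random lists of protein-coding genes. PCDH7 had -1.24 ± 0.13, PCDH9 -2.48 ± 0.32 and N-cadherin, CDH2, 1.202 ± 0.17. For epithelial junction and keratin genes, 6 were higher and 5 lower among 30 measured members, and 6 and 6 when adjusted over the list alone, with a median of -0.055 at percentile 36.1. Cingulin, CGN, had 1.001 ± 0.17, the desmosomal genes DSC2 and PKP3 0.67 ± 0.15 and -0.71 ± 0.13, and KRT7 -0.70 ± 0.15. For mesenchymal genes, 7 were higher and 5 lower among 29 measured members, and 7 and 5 when adjusted over the list alone, with a median of 0.25 at percentile 93.6. WNT5A had -1.27 ± 0.14, SPOCK1 -1.28 ± 0.17 and S100A4 -1.71 ± 0.23, while CDH2, also a member of this list, was higher at 1.202 ± 0.17. The mean of the list was -0.0069, opposite in sign to its median. For gap junction genes, 2 were higher and 3 lower among 12 measured members, and 2 and 3 when adjusted over the list alone, with a median of -0.38 at percentile 4.39, and at 1.05 against random lists of protein-coding genes, 1.57 against lists matched on implied standard error and 2.37 with the length and GC trend removed. The connexin genes GJC1 and GJB5 had 1.46 ± 0.14 and -0.96 ± 0.19, and the pannexin genes PANX1 and PANX2 0.51 ± 0.16 and -0.70 ± 0.14. For integrin and basement membrane genes, 9 were higher and 5 lower among 30 measured members, and 9 and 5 when adjusted over the list alone, with a median of 0.11 at percentile 75.8. Among them were LAMA4 at -1.54 ± 0.15, ITGA5 at 1.31 ± 0.18 and ITGB5 at -0.85 ± 0.12. For metalloproteinases and proteases, 3 were higher and 6 lower among 30 measured members, and 3 and 6 when adjusted over the list alone, with a median of 0.073 at percentile 68.7, against a mean of -0.078. ADAM12 had -1.69 ± 0.19, cathepsin S, CTSS, 4.63 ± 0.60 and TIMP2 0.91 ± 0.12.

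Signalling and damage-response lists were mixed. For TGF-beta/SMAD target genes, 3 were higher and 11 lower among 30 measured members, and 3 and 11 when adjusted over the list alone, with a median of -0.11 at percentile 24. CTGF, a matricellular growth factor, had -1.31 ± 0.17, LTBP2 -0.84 ± 0.12, LTBP3 -0.73 ± 0.11 and THBS1 -0.64 ± 0.11. For YAP/TEAD target genes, 4 were higher and 11 lower among 30 measured members, and 5 and 11 when adjusted over the list alone, with a median of -0.089 at percentile 28.2. IGFBP3 had -2.16 ± 0.15, MYOF -0.77 ± 0.11 and the kinase gene NUAK2 2.04 ± 0.18. For p53 target genes, 5 were higher and 2 lower among 30 measured members, and 7 and 2 when adjusted over the list alone, with a median of 0.014 at percentile 53.4. The cell cycle inhibitor CDKN1A had 1.01 ± 0.14, BTG2 1.43 ± 0.21, POLH 0.90 ± 0.18 and AEN -0.75 ± 0.17. For apoptosis genes, 10 were higher and 3 lower among 28 measured members, and 10 and 3 when adjusted over the list alone, with a median of 0.18 at percentile 87. BMF had 0.99 ± 0.25 and survivin, BIRC5, -0.45 ± 0.11. For calcium channels and pumps, 3 were higher and 1 lower among 26 measured members, and 3 and 1 when adjusted over the list alone, with a median of 0.082 at percentile 69.8. CACNG4 had -0.97 ± 0.13, ATP2B4 0.54 ± 0.11, ITPR2 0.81 ± 0.21 and CACNA1H 0.90 ± 0.32. For genes tied to brain metastasis, 6 were higher and 5 lower among 25 measured members, and 6 and 6 when adjusted over the list alone, with a median of -0.053 at percentile 37.5, against a mean of 0.34. C3, PCDH7, L1CAM at 1.21 ± 0.14 and lipocalin 2, LCN2, at 1.54 ± 0.15 had the smallest adjusted p values of that list.

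Metabolic lists included sterol genes that were higher in group 8. For cholesterol synthesis genes, 11 were higher and 0 lower among 24 measured members, and 12 and 0 when adjusted over the list alone, with a median of 0.31 at percentile 95.4. MSMO1 had 1.49 ± 0.14, squalene epoxidase, SQLE, 0.96 ± 0.12, HMGCS1 0.99 ± 0.14 and INSIG1 0.95 ± 0.16. For hypoxia-response genes, 11 were higher and 3 lower among 28 measured members, and 11 and 3 when adjusted over the list alone, with a median of 0.33 at percentile 97.2. NDRG1 had 1.29 ± 0.16, STC1 2.18 ± 0.30 and BNIP3 0.76 ± 0.13, whereas the glucose transporter SLC2A1 was lower at -0.80 ± 0.13. Against random lists of protein-coding genes, the cholesterol and hypoxia lists lay at percentiles 98.1 and 99.3. For glycolysis genes, 6 were higher and 6 lower among 24 measured members, and 6 and 7 when adjusted over the list alone, with a median of -0.13 at percentile 20.6, against a mean of 0.077. PFKFB4 had 0.9997 ± 0.19, ALDOC 1.09 ± 0.21 and ENO2 0.82 ± 0.16. For fatty acid synthesis and lipid storage genes, 3 were higher and 5 lower among 24 measured members, and 4 and 5 when adjusted over the list alone, with a median of 0.059 at percentile 63.3. ACSL4 had 1.10 ± 0.15, SREBF1 -0.88 ± 0.14, ACSL3 -0.61 ± 0.15 and DGAT2 0.71 ± 0.18. For unfolded protein response genes, 1 was higher and 3 lower among 20 measured members, and 1 and 5 when adjusted over the list alone, with a median of -0.20 at percentile 11.4. ATF4 had -0.62 ± 0.14, DNAJB9 0.61 ± 0.21 and PDIA4 -0.34 ± 0.12, while CRELD2 at -0.44 ± 0.17 lost its call when every deposited p-value entered the adjustment. For amino acid response genes, 3 were higher and 7 lower among 30 measured members, and 3 and 7 when adjusted over the list alone, with a median of -0.022 at percentile 44.1, against a mean of 0.067. The amino acid transporter genes SLC7A5 and SLC3A2 had -1.76 ± 0.13 and -0.77 ± 0.13, ATF5 -1.52 ± 0.16 and CEBPB 0.92 ± 0.13.

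Called mitochondrial and ribosomal genes were lower in group 8. For mitochondrially encoded genes, 0 were higher and 6 lower among 13 measured members, and 0 and 6 when adjusted over the list alone, with a median of -0.43 at percentile 2.79. That list lay outside the middle 95% against random lists of protein-coding genes, at percentile 0.49, and against lists matched on implied standard error, at 0.17. It lay inside by the mean of members, at 9.05. Centring gave 2.47, but it shifted only the list's median and not the random medians, so that crossing decides nothing. MT-CO3 had -0.78 ± 0.13, MT-ND2 -0.61 ± 0.17, MT-CO2 -0.46 ± 0.13 and MT-ND3 -0.47 ± 0.14. For nuclear oxidative phosphorylation genes, 0 were higher and 2 lower among 32 measured members, and 0 and 2 when adjusted over the list alone, with a median of -0.14 at percentile 17.4. CYC1 had -0.48 ± 0.14 and UQCRFS1 -0.36 ± 0.11. For ribosomal protein genes, 0 were higher and 6 lower among 35 measured members, and 0 and 5 when adjusted over the list alone, with a median of -0.17 at percentile 12.2. RPLP2 had -0.49 ± 0.14, RPS12 -0.45 ± 0.13 and RPS23 -0.66 ± 0.21. For replication-dependent histone genes, 1 was higher and 0 lower among 17 measured members, and 1 and 0 when adjusted over the list alone, with a median of -0.0034 at percentile 49. HIST1H2AC had 1.17 ± 0.18, and poly-A selection recovers these transcripts poorly.

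Markers of other cell types gave few calls. For astrocyte and neural markers, 1 was higher and 1 lower among 12 measured members, and 1 and 1 when adjusted over the list alone, with a median of 0.23 at percentile 82.8. SLC1A3 had 0.85 ± 0.18 and MAP2 -0.74 ± 0.17. For fibroblast markers, 1 was higher and 0 lower among 10 measured members, and 1 and 0 when adjusted over the list alone, with a median of 0.35 at percentile 89.1, the call being COL1A1 at 1.04 ± 0.17. For endothelial markers, 0 were higher and 1 lower among 11 measured members, and 0 and 0 when adjusted over the list alone, with a median of 0.34 at percentile 88.7. PECAM1 at -1.73 ± 0.63 lost its call when every deposited p-value entered the adjustment.

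**Figure D3:**
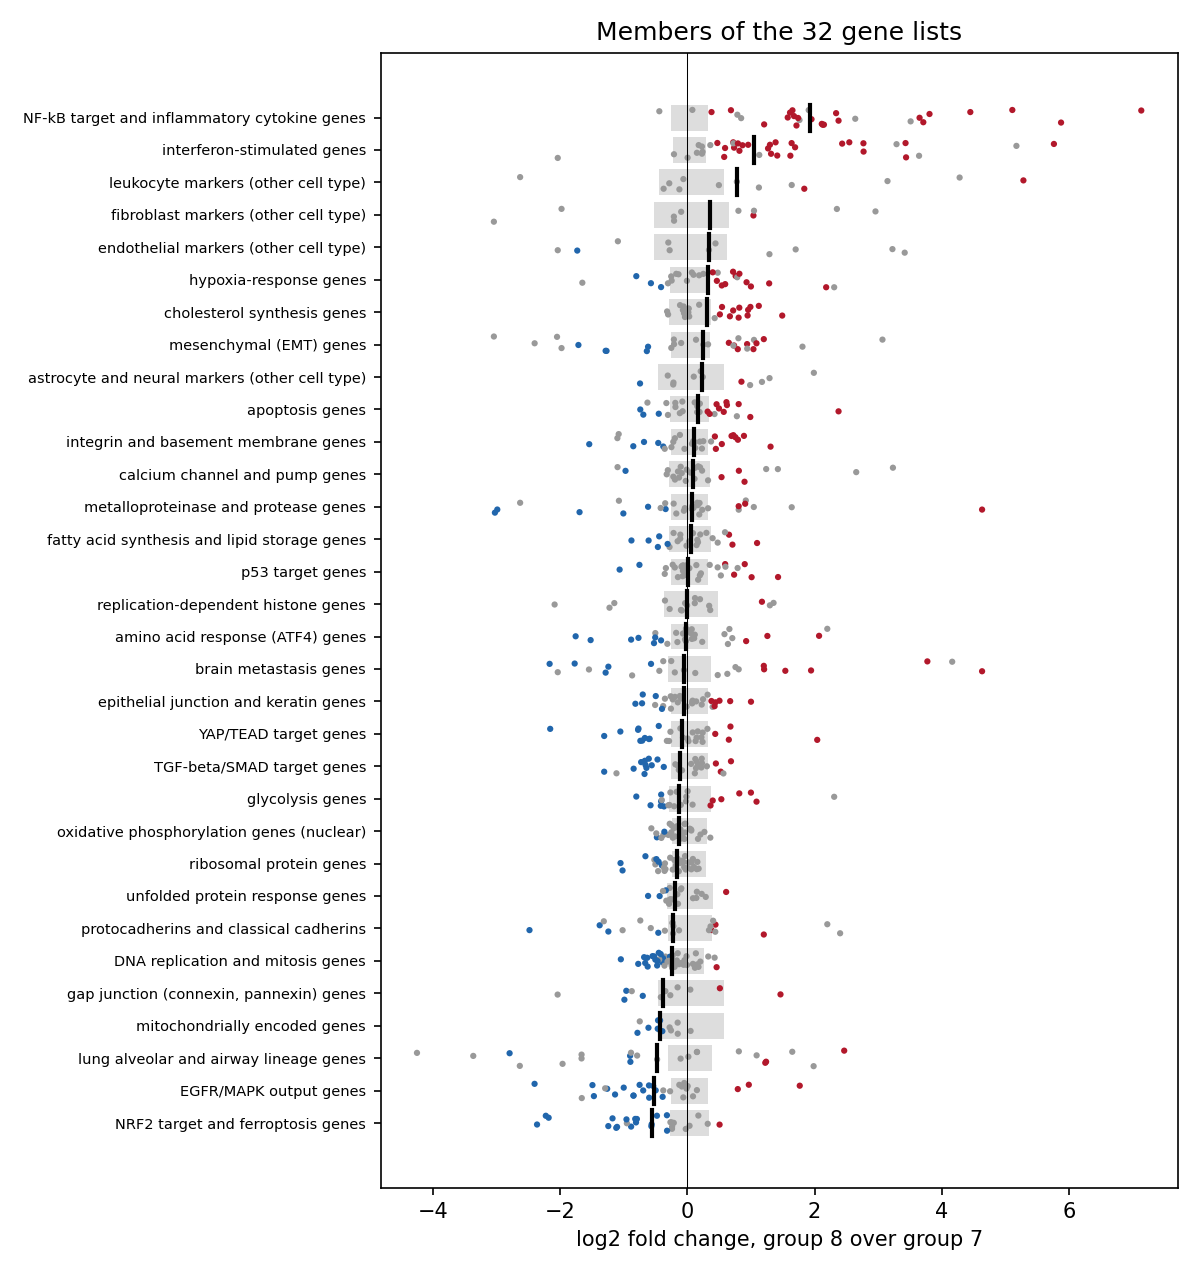
Each row is one of 32 gene lists, each point a measured member placed by log2 fold change of group 8 over group 7, red or blue where its adjusted p was under 0.05 and grey otherwise. Black bars mark list medians and light bands the middle 95% of medians of 10000 random lists of the same size, with the NF-kB list at 1.93 and the NRF2 list at -0.56.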

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

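Tests with random lists matched on implied standard error, with the length and GC trend removed and without genes holding GACGTC were chosen only after results were seen. Calls numbered 2547 (1222 higher, 1325 lower) at an adjusted p under 0.01 and 1078 (647 higher, 431 lower) with an absolute log2 fold change of at least 1, in both cases because the criterion is stricter. The other 5 alternatives left the total between 2996 and 4934. Against random lists of protein-coding genes, medians passed outside the middle 95% for the cadherin (-0.22), gap junction (-0.38), hypoxia (0.33), cholesterol (0.31) and mitochondrial (-0.43) lists. Matched on implied standard error, the same happened for gap junction (-0.38), hypoxia (0.33), cholesterol (0.31) and mitochondrial (-0.43) lists, while the leukocyte list (0.78) came inside. The mitochondrial list also passed when centred (-0.45), but centring shifted only its own median and not the random medians, so that crossing decides nothing. The gap junction list passed with the trend removed (-0.43). The replication list came inside with means (-0.24), and the lung lineage (-0.29) and leukocyte (0.53) lists over protein-coding members with an adjusted p below 1. Centring aside, the cause of these shifts was not tested. No list passed to the opposite side under any of these 6 alternatives. Of 133 named genes besides PCDH1, 2 (CRELD2 and PECAM1) lost their call with adjustment over every deposited p-value, and PCDH1 kept its call. Centring moved values by only 0.017, less than the size of any named gene's log2 fold change, so no sign could change. Not run, because no library or level was mapped to a label, were the edgeR and DESeq2 fits, leaving out libraries, filters on mean level and folds from group means. No paired analysis was run because no label ties the libraries into pairs. Unmatched random lists, foreseen as an alternative, became the main setting because no level was used. Depth was not used and its limit is not given.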

Other observations

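Among the tests here, those of leukocyte transcripts and of the share of each decrease taken by the trend were chosen only after results were seen, and the trend removal was added after seeing the data. The gene sets, the definition of strong decreases and the settings of the word search were also chosen after values had been seen, and the strand test after the word search. All values come from the authors' deposited table as group 8 over group 7, with implied standard errors.

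Some antigen presentation and complement genes were higher in group 8. For MHC class I presentation genes, 13 were higher and 0 lower among 21 measured members, and 15 and 1 when adjusted over the list alone, with a median of 0.47. The member lower on its list alone was CALR at -0.29 ± 0.12. Besides HLA-B, B2M, the invariant class I chain, had 1.24 ± 0.10, the peptide transporter TAP1 1.34 ± 0.17 and the immunoproteasome subunit PSMB9 1.77 ± 0.20, while HLA-C had 0.45 ± 0.15. For complement and acute-phase genes, 9 were higher and 1 lower among 19 measured members, and 10 and 1 when adjusted over the list alone, with a median of 0.99. C1S had 2.23 ± 0.14, C1R 1.89 ± 0.18 and factor B, CFB, 3.76 ± 0.40, whereas factor D, CFD, was lower at -0.88 ± 0.15.

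Some secretory epithelial genes were lower in group 8. For mucin, trefoil and CEACAM genes, 1 was higher and 8 lower among 18 measured members, and 1 and 8 when adjusted over the list alone, with a median of -1.32. AGR2, a secretory protein disulfide isomerase, had -2.003 ± 0.17, CEACAM6 -2.61 ± 0.16, the transcription factor SPDEF -1.84 ± 0.25 and TFF1 -2.48 ± 0.55, while MUC1 was higher at 1.23 ± 0.17. For aldehyde and retinoid metabolism genes, 0 were higher and 6 lower among 16 measured members, and 0 and 6 when adjusted over the list alone, with a median of -0.26, with ALDH1A3 at -1.08 ± 0.15 and DHRS3 at -0.75 ± 0.13. For subunits of the TRiC chaperonin and the 20S proteasome core, 1 was higher and 4 lower among 22 measured members, and 1 and 4 when adjusted over the list alone, with a median of -0.065. CCT3 had -1.95 ± 0.13 while the other chaperonin subunits ran from -0.48 ± 0.099 (CCT6A) to -0.0095 ± 0.11 (CCT8), and PSMA4 had -1.59 ± 0.11 while the other core subunits ran from -0.16 ± 0.29 (PSMA2) to 0.27 ± 0.10 (PSMB4).

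The NF-kB and interferon lists were higher in group 8. A length or GC trend is argued against as the whole source, since after its removal both medians stayed at percentile 100 of random lists. Leukocytes among the cells stay open for both lists: the leukocyte marker list had a median of 0.78 at percentile 99.3. Of its 13 measured members, 2 were called higher, ITGAM at 5.28 ± 0.85 and CSF1R at 1.84 ± 0.24. That list came inside the middle 95% of random lists when matched on implied standard error. It also did so over protein-coding members with an adjusted p below 1. CD14, CD68 and PTPRC were not called. The upper 95% bounds of CD14 (0.93) and PTPRC (1.22), the 2 with an adjusted p below 1, lay below the NF-kB median of 1.93. Only that of CD14 lay below the interferon median of 1.04, and the bound of CD68, 3.41, was above both medians. CD14 and PTPRC thus gave no rise of the size of the NF-kB list, but ITGAM and CSF1R go the other way, so leukocytes are not excluded. A difference between cultures or a response to either hairpin may also give these values, and no label allows these to be told from an effect of PCDH1 loss.

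A set of 132 protein-coding genes was lower by at least 1 (log2) with an implied standard error of at most 0.2, CCT3 and PSMA4 among them. A single short RNA seed behind the whole set was tested among 3' UTR hexamers expected in under 30% of it. The best, GACGTC, exceeded its expected share by 13.3 percentage points, short of the 50 asked for. This argues against such a seed, while commoner hexamers and sites outside the searched 3' UTRs were not covered. A length and GC trend took at most 26.1% of any of these decreases, which argues against it as the larger part of them. After its removal 84.8% of the set stayed lower by at least 1, short of the 90% asked for. That test does not decide whether the trend made part of the decreases. A seed behind part of the decreases is a candidate explanation: GACGTCA was the 7-base word most tied to lower values, with a t-like score of -7.93 against -5.34 for the most extreme of 1000 shufflings. The 62 genes with GGACGTCA had a mean log2 fold change, adjusted for length and GC, of -0.42 ± 0.069 (SE over genes), with 33 lower and 0 higher calls, against 0.010 ± 0.0053 for 12587 genes without GACGTC. GGACGTCA joins the 7-base words GACGTCA and GGACGTC, which were picked as most tied to lower values on these same genes. Its low mean and calls therefore follow in part from that choice and are no separate support for a seed. A DNA element read on either strand stays open: genes with the 7-base words differed by -0.13 ± 0.049 from the 254 genes with only their reverse complements, but the words were chosen on these genes, and those 254 lay at -0.12 ± 0.036 against 0.0015 ± 0.050 for 134 genes with GACGTC but neither the words nor these complements.

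Of the genes in that set, 25 of the 131 with a searched 3' UTR hold GACGTC, among them PCDH1, CCT3, PSMA4, GPN1, SLC7A5, JAG1, ANXA1, AKR1C3, AHR and MNT. Without GACGTC genes, 1795 genes were higher and 1802 lower in group 8. The word was picked as tied to lower values on these same genes, so this split follows in part from that choice. It is no separate support for a seed. Genes with GGACGTCA outside the 3' UTR and no GACGTC within it, 287 in number, had a mean of -0.16 ± 0.033. For genes with only the shorter words there, means were -0.092 ± 0.025 (GACGTCA), -0.023 ± 0.026 (GGACGTC) and 0.0071 ± 0.020 (GACGTC). The searched 3' UTR of PCDH1 holds GACGTC but not GGACGTCA, which lies elsewhere in 2 of its 3 basic protein-coding transcripts. Over whole transcripts, 3.09% of the 13381 searched genes hold GGACGTCA in at least 1. That share is not matched to PCDH1 on length, GC or number of transcripts, so it does not tell how unusual the PCDH1 site is. The hairpin sequences were not used here, so whether either carries such a seed was not tested.

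The replication list was lower in group 8 and the ribosomal and mitochondrial lists had medians below 0 inside the middle 95% of random lists drawn from all genes. For the replication list a length and GC trend is argued against as the whole source, since the list lay at percentile 0.25 after its removal. For the ribosomal and mitochondrial lists, at percentiles 11.3 and 5.17 after removal, the test decides nothing, since neither was outside against such lists before it, although the mitochondrial list was outside under other settings. Slower growth of the group 8 cells may account for the replication list, which was not tested, and no biological explanation was tested for the others.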
